A study of Mus musculus with 6 samples.

How the data were processed

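RNA of bone marrow-derived macrophages, 3 control samples and 3 exposed to 100 µM ADP for 6 h, was measured on one-colour Agilent mouse arrays, 1 array per sample. Groups and replicate numbers came from the sample titles. Per the file headers, the deposited intensity of each spot was extracted with Agilent Feature Extraction 10.7.1.1, the version that the submitters' processing notes also name, under a one-colour protocol that corrects spatial trends and subtracts background within the array. The deposited intensity files were not scaled between arrays. A value table for the whole series was also deposited. Its intensities were within 0.001 log2 of the mean log2 processed signal of each probe's spots for 100% of 55681 probes on each array, so it is the same signal on a linear scale, unscaled between arrays and with its direction known, and its column medians were 18.5, 20.2 and 21.8 for controls 1 to 3 and 20.6, 21.7 and 22.5 for ADP 1 to 3. Flags for spots well above background, saturated or non-uniform came from the deposited files.

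Here, control spots were left out, and so were spots marked as outliers, unless all spots of the probe were marked. Spots of one probe were averaged, and the log2 processed signal was taken relative to the 75th percentile of each array. A probe was kept when it was well above background on all 3 arrays of at least 1 group, which left 26587 probes. Each gene was represented by its probe with the highest mean over the 6 arrays. Of 4897 genes with several such probes, 5 had probes at an unadjusted p under 0.05 in opposite directions. Probe names were updated through a RefSeq gene table of assembly GRCm38.p6, used for names alone. Of the 55681 probes, 26582 were named through their accession, 2602 carried a current symbol, 492 carried a synonym and 26005 kept the name in the file. Of the genes on the lists, 8 matched no name on the array. Coordinates are those of the probes in the files, on mouse build mm9.

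Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, without a block, over 19575 features, with Benjamini-Hochberg adjustment and a threshold of 0.05. A simple permutation of 3 against 3 arrays could not go below p = 0.1. The submitters describe independent experiments on different donors, and the labels do not say that a replicate number marks a shared donor. The 39 gene lists, written before the data were examined, were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 39 lists. Every list had at least 5 measured members, and 709 of the 809 listed genes were measured. The camera test compares a list with all other genes. In fry, a list is tested on its own. Random lists for comparison were drawn 10000 times from genes of similar mean signal.

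The rule for named genes took the 10 genes higher and the 10 lower with the largest change among those past the threshold. As none passed, the 10 in each direction with the smallest unadjusted p were taken, among genes whose groups did not overlap and whose symbol was not that of a clone, predicted gene or accession. The rule added the member with the smallest p of each list, the ADP receptor genes P2ry1, P2ry12 and P2ry13, and Ccl2. Where a probe was not well above background on any array of a group, the fold is a lower bound, from the mean of the brighter group against the higher of the dim probe's own signal and the lowest signal well above background on each array. Such a bound holds for the processed signal used here and not for other background corrections.

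The files showed 2 slides, each with both groups, so the slide was fitted as a block and differences were taken within each slide. Other alternatives were normexp background correction with an offset of 50, quantile normalization, the median in place of the 75th percentile, the unscaled value table, no filter on dim probes, a filter on all 6 arrays, the mean of a gene's probes, each probe on its own, trended and robust variances, the replicate number as a block, and leaving out each array in turn. The slide as a block together with quantile normalization, or with trended and robust variances, was added after the data were seen.

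The fit was tested on simulated data with the real levels and slide shifts of the 19575 features, in 5 simulations with 100 genes changed 2-fold and 100 changed 4-fold. Spreads were drawn at random from the distribution that limma fitted to the real ones, unlinked to gene or signal. Genes varied independently, so the recovery below is that of an idealised case. Without a block it recovered 41.6% of the 2-fold and 85.4% of the 4-fold changes, and with the slide block 72.6% and 94.0%. The list test recovered 20 of 20 lists shifted by 0.5 on the log2 scale and called 1 other list. That shift was larger than any real list median on all arrays, the largest being 0.31 for the NRF2 oxidative stress list. Since the simulated genes held no correlation, this result cannot tell how often the list test calls falsely where genes of a list vary together. Figures were drawn with matplotlib 3.10.9.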

Results

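Macrophages grown from the bone marrow of C57BL/6 mice were exposed to 100 µM ADP, a nucleotide released by damaged and activated cells, and their RNA was compared after 6 h with that of control macrophages. Each group held 3 samples, described by the submitters as independent experiments on different donors, and each sample was hybridised to its own one-colour microarray. The question was which transcripts differ when macrophages meet extracellular ADP. Between 50.3% and 51.9% of the 59305 non-control spots were well above background on each array, no spot was saturated, and the 75th percentile of the signal ranged from 455 to 549. The number of arrays, 3 per group, limits the precision of every value below. Levels are log2 signals relative to the 75th percentile of the array, and differences are ADP minus control on the log2 scale.

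The 6 arrays came from 2 slides, and both slides held both groups. Slide 1 carried controls 1 and 2 and ADP 1, and slide 2 carried control 3 and ADP 2 and 3. The first principal component, with 44.9% of the variance, separated the slides. The second, with 31.2%, separated the treatments. Controls scored 24.0, 9.83 and 32.0 on it and ADP arrays scored -22.4, -12.0 and -31.4. Across genes, which are not independent replicates, pairs of arrays of one group on one slide correlated at r = 0.996 to 0.997. Pairs of one group on different slides correlated at 0.988 to 0.990. Values with the slide as a block and within each slide are therefore given beside the pooled ones.

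**Figure D1:**
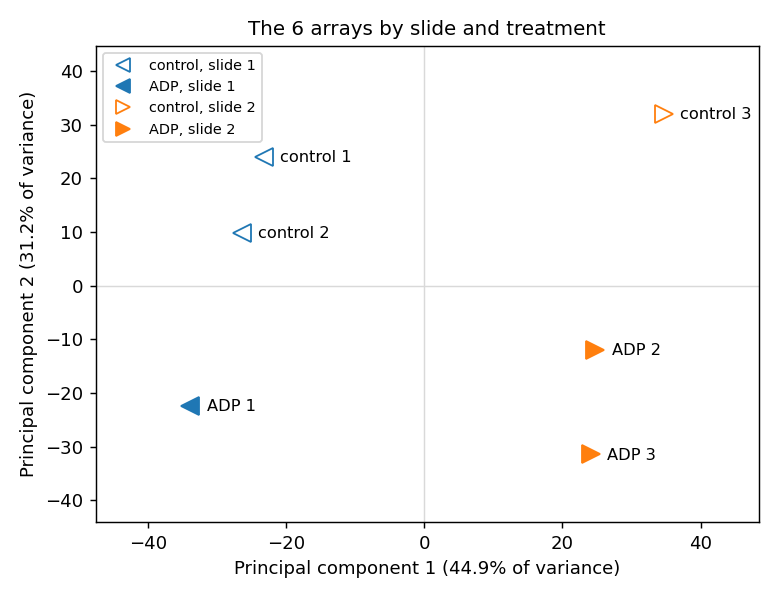
Scores of the 6 arrays on the first principal component (horizontal axis, 44.9% of variance) and the second (vertical axis, 31.2%), computed on the log2 values of all tested genes. Left-pointing triangles are slide 1, right-pointing triangles slide 2, filled symbols ADP and open symbols control, and the 3 ADP arrays lie below 0 on the second component while the 3 controls lie above it.

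Transcripts for the cytokines Il1b and Csf3 and for the growth factor Vegfa read higher on the ADP arrays, by 1.43 ± 0.38, 1.59 ± 0.41 and 1.39 ± 0.34 (log2, SE, n = 3 arrays per group), and those for cyclin D1 (Ccnd1) and the prostaglandin-degrading enzyme Hpgd read lower, at differences of -1.60 ± 0.31 and -1.31 ± 0.26. Each of these genes had the smallest p of a list described below, and none was among the genes ranked by p over all features. Differences within slides 1 and 2 were 1.00 and 2.27 for Il1b, 1.45 and 2.27 for Csf3, and 1.12 and 2.07 for Vegfa. They were -1.68 and -1.64 for Ccnd1 and -1.39 and -1.40 for Hpgd. Over all settings run the lowest difference was 1.01 for Il1b and 1.02 for Vegfa. Csf3 was well above background on 2 of 3 control arrays, and with normexp background correction its difference was 0.65. No gene passed the test after adjustment. Of 19575 features tested, 13377 of them named genes, limma called 0 at a Benjamini-Hochberg adjusted p under 0.05, and therefore 0 with at least a 2-fold difference. The smallest adjusted p, 0.260, was shared by 245 features. At an unadjusted p under 0.05 there were 2492 features, 1282 higher and 1210 lower with ADP, where 978.75 were expected by chance. With the slide as a block the count was again 0, with a smallest adjusted p of 0.0734 shared by 691 features, and 4759 had an unadjusted p under 0.05, 2106 higher and 2653 lower. In the value table without scaling between arrays, 1228 were higher and 326 lower at an unadjusted p under 0.05. Groups did not overlap for 3796 features, or 19.4%, where chance gives 10% with 3 arrays against 3. At least a 2-fold difference was seen for 229 features higher with ADP and 66 lower, of which 198 and 48 also had an unadjusted p under 0.05. One setting chosen after the data were seen, the slide as a block together with intensity-trended, robust variances, called 1939 genes, 885 higher and 1054 lower, of which 296 differed at least 2-fold. The count at an unadjusted p under 0.05 was 1381 without control 1 and 1163 without ADP 3.

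None of the 10 genes with the smallest p among those higher with ADP passed (adjusted p = 0.260). Of those well above background in both groups, the largest difference was that of Calca, which encodes calcitonin and the calcitonin gene-related peptide. Its probe (chromosome 7, 121776948 to 121777007, mouse build mm9) read -4.26 ± 0.30 in controls and -2.57 ± 0.27 with ADP (SD, n = 3 each), a 3.23-fold difference, with log2 differences of 1.52 and 1.97 within slides 1 and 2. Ager, the receptor for advanced glycation end products (chromosome 17, 34735715 to 34735876), was not well above background on any control array and was at least 1.82-fold higher with ADP. Ptgis, which encodes prostacyclin synthase, and the claudin gene Cldn15 were likewise not well above background in controls and were at least 2.37-fold and 2.39-fold higher. The log2 difference was 1.02 ± 0.13 (SE) for the phospholipase C-like gene Plcl1, 1.18 ± 0.17 for the chromatin-complex subunit gene Dpf1 and 1.04 ± 0.17 for the olfactory receptor gene Olfr1410. Mtmr7 differed by 0.81 ± 0.13, the zinc-finger gene Zfp667 by 0.70 ± 0.10 and the co-chaperone gene Sgtb by 0.68 ± 0.10. Several of these probes were dim, with control levels of -4.26 for Calca and -4.47 for Plcl1. With normexp background correction the log2 differences of all 10 were over 1.5 times smaller, from 0.23 for Zfp667 to 0.74 for Calca, with 0.29 for Ager, 0.41 for Ptgis and 0.38 for Cldn15, so the sizes and bounds above depend on the background method.

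The 10 genes with the smallest p among those lower with ADP (adjusted p = 0.260 each) included Etl4, at -1.04 ± 0.22 in controls and -2.34 ± 0.43 with ADP (SD, n = 3 each), a 2.46-fold difference (probe on chromosome 2, 20731861 to 20731920). Cacna1a, the pore-forming subunit of a neuronal voltage-gated calcium channel, differed by -0.70 ± 0.12 (log2, SE). Zeb1, a transcription factor of epithelial-mesenchymal transition, differed by -0.69 ± 0.12, the phospholipid scramblase gene Plscr4 by -0.67 ± 0.10 and Nhlrc1, which encodes the ubiquitin ligase malin, by -0.55 ± 0.10. The zinc-finger genes Zfp395 and Zfp783 differed by -0.88 ± 0.13 and -0.87 ± 0.16, Vsig10l by -1.19 ± 0.17 and Ifrd2 by -0.71 ± 0.13. Myh10, a non-muscle myosin heavy chain, was not well above background on any ADP array and was at least 1.29-fold lower there. With normexp background correction the differences were -0.47 for Vsig10l, -0.45 for Cacna1a, -0.44 for Zfp783, -0.41 for Zeb1 and -0.20 for Myh10. The slide-blocked adjusted p of all 20 genes, higher and lower, was 0.0734, and 19 of the 20 were among the 1939 called in the slide-blocked setting with trended, robust variances.

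Genes were also read as 39 lists fixed before the data were examined. With camera at a preset inter-gene correlation of 0.01, 6 lists shifted at an adjusted p under 0.05. Antioxidant and cholesterol synthesis genes shifted higher, and interferon-stimulated, ribosome biogenesis, calcium-NFAT signalling and cell cycle genes shifted lower. With an estimated correlation no list passed (smallest adjusted p = 0.347), and fry called 1 list for a shift in one direction, the NRF2 list, and 17 for change in either direction. In the slide-blocked fit, camera with the preset correlation called 7 lists, camera with an estimated correlation 0 (smallest adjusted p = 0.593), and fry 0 (smallest adjusted p = 0.0754). No member of any list passed over all genes tested, with or without the slide block at untrended variances, so single members are given as values. In 30 of the 33 lists that did not pass, the median turned sign or moved by over 1.5 times with 1 array left out. Those named beyond the smallest p of each list were chosen after their values were seen.

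Genes of the NRF2 oxidative stress response, which encode enzymes that supply glutathione and remove peroxides and electrophiles, shifted higher as a list. Its median log2 difference was 0.31 (adjusted p = 1.72e-04, camera), and 20 of 24 measured members were above 0. Txnrd1, thioredoxin reductase, had the smallest p of the list, at 5.76 ± 0.06 in controls and 6.34 ± 0.19 with ADP (SD, n = 3 each). Slc7a11, the cystine transporter, differed by 1.29 ± 0.37 (log2, SE), the sulfiredoxin gene Srxn1 by 0.55 ± 0.15, the quinone reductase gene Nqo1 by 0.50 ± 0.15 and Osgin1 by 0.38 ± 0.10. The median was 0.22 with the slide as a block (adjusted p = 6.37e-04), 0.25 within slide 1 and 0.23 within slide 2. Adjusted over the list alone, 0 members passed without the block and 9 passed with it, all higher. The median was 0.20 with quantile normalization. The adjusted p was 0.347 with an estimated correlation and 0.0105 in fry.

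Cholesterol synthesis genes shifted higher by a smaller amount, with a median of 0.19 (adjusted p = 1.72e-04, camera) and 21 of 23 measured members above 0. Cyp51 differed by 0.36 ± 0.15 (log2, SE), Fdft1 by 0.34 ± 0.11, Idi1 by 0.30 ± 0.11 and Hmgcs1 by 0.29 ± 0.11. The median was 0.24 with the slide as a block (adjusted p = 5.74e-04), 0.24 within slide 1 and 0.19 within slide 2. Without the block 0 members passed adjusted over the list alone, and with it 6 were higher and 1 lower. The adjusted p was 0.662 with an estimated correlation.

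Interferon-stimulated genes shifted lower, with a median of -0.19 (adjusted p = 6.63e-05, camera) and 31 of 39 measured members below 0. Mx1, an antiviral GTPase, differed by -0.80 ± 0.21 (log2, SE), Cmpk2 by -0.68 ± 0.20, Ifi203 by -0.61 ± 0.15, Ifit3 by -0.55 ± 0.17 and Stat2, a subunit of the interferon-activated transcription factor, by -0.36 ± 0.10. The median was -0.28 with the slide as a block (adjusted p = 7.42e-07), -0.25 within slide 1 and -0.27 within slide 2. No member passed adjusted over the list alone without the block, and 14 passed with it, all lower. The adjusted p was 0.662 with an estimated correlation, and the median was -0.29 without ADP 2 and -0.11 in the unscaled value table. The list of type I interferons and their receptors did not pass (adjusted p = 0.283, camera), with a median of -0.05 (-0.15 with the slide as a block, -0.01 and -0.26 within slides 1 and 2), and its smallest p belonged to Ifngr1, the interferon-gamma receptor gene, at -0.37 ± 0.10. That list passed only in the slide-blocked setting with trended, robust variances (adjusted p = 0.0492).

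Ribosome biogenesis genes, which encode nucleolar factors that process and assemble ribosomal RNA, also shifted lower. The median was -0.23 (adjusted p = 1.72e-04, camera), and 21 of 22 measured members were below 0. Ppan differed by -0.32 ± 0.10 (log2, SE), Nop2 by -0.37 ± 0.13, Nolc1 by -0.34 ± 0.12, Rrp12 by -0.44 ± 0.19 and Gnl3 by -0.23 ± 0.11. The median was -0.31 with the slide as a block (adjusted p = 6.14e-06), -0.24 within slide 1 and -0.39 within slide 2. Adjusted over the list alone, 0 members passed without the block and 8 passed with it, all lower. The adjusted p was 0.662 with an estimated correlation, and the median was -0.15 in the unscaled value table. Rrp12 differed by -0.28 without control 2 and by -0.27 with normexp correction.

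Genes of calcium and NFAT signalling downstream of G-protein-coupled receptors shifted lower, with a median of -0.24 (adjusted p = 0.00724, camera) and 14 of 18 members below 0. The transcription factor gene Nfatc2 differed by -0.61 ± 0.13 (log2, SE), Egr2 by -0.60 ± 0.14, Rgs18, a regulator of G-protein signalling, by -0.49 ± 0.12, Camk1 by -0.44 ± 0.13 and the plasma membrane calcium pump gene Atp2b1 by -0.37 ± 0.13. The median was -0.29 with the slide as a block (adjusted p = 0.0102), -0.26 within slide 1 and -0.23 within slide 2. Adjusted over the list alone, 3 members passed without the block and 9 with it, all lower. The adjusted p was 0.662 with an estimated correlation, 0.0768 without control 3 (median -0.15) and 0.134 without ADP 1 (median -0.12), so the size and the call both depended on single arrays.

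The cell cycle list passed narrowly, with a median of -0.12 (adjusted p = 0.0455, camera), and 22 of 32 members were below 0. Ccnd1, which encodes cyclin D1, differed by -1.60 ± 0.31 (log2, SE), and the replication licensing genes Mcm2, Mcm3 and Mcm5 by -0.50, -0.41 and -0.46, while the centromere gene Cenpa differed by 0.44 ± 0.16 (0.28 without ADP 1). The median was -0.12 with the slide as a block (adjusted p = 0.285), 0.03 within slide 1 and -0.29 within slide 2. The sign thus turned between the slides, and the call was lost with the block. Adjusted over the list alone, 0 members passed without the block, and 1 was higher and 2 were lower with it. The adjusted p was 0.662 with an estimated correlation, 0.150 without control 1, 0.123 without control 3 (median -0.08), 0.147 without ADP 2 and 0.167 without ADP 3. It was smaller, at 0.00455 without control 2 (median -0.21), and at 0.00530 without ADP 1 (median -0.19). Under other choices of processing it was 0.0642 with normexp correction, 0.0536 with median scaling, 0.0730 in the value table (median -0.04), and 0.0662 and 0.0780 with the mean of probes and every probe. With the replicate number as a block it was 0.0768.

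**Figure D2:**
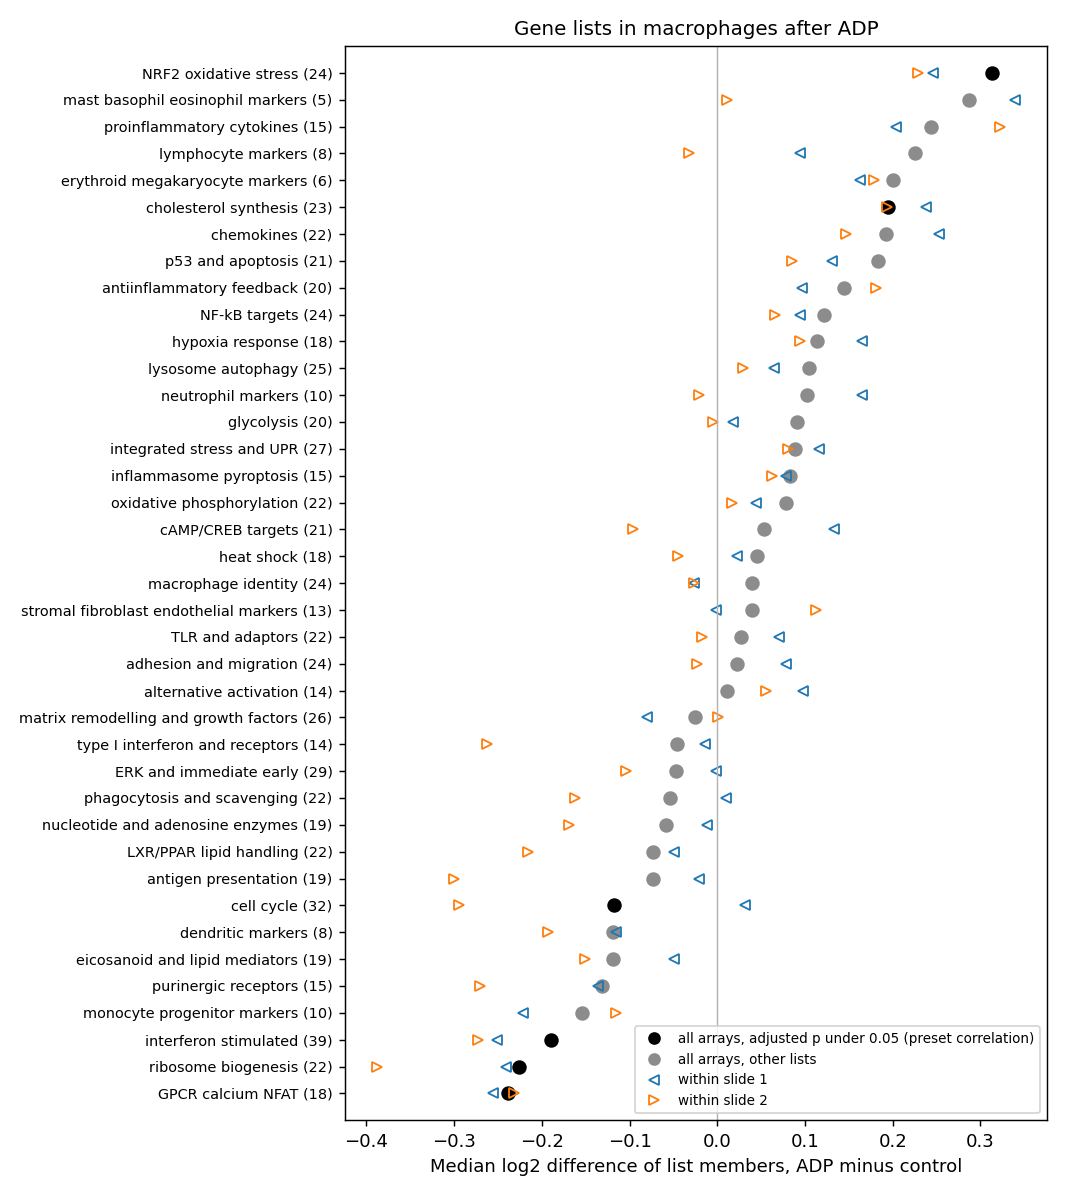
Median log2 difference (horizontal axis, ADP minus control) of the members of each of the 39 gene lists, with the number of measured members in parentheses. Circles are all 6 arrays, black for the 6 lists with an adjusted p under 0.05 in camera with the preset correlation, and open triangles are the medians within slide 1 and slide 2. The NRF2 list is highest at 0.31, the calcium-NFAT list is lowest at -0.24, and the cell cycle median lies at 0.03 within slide 1 and -0.29 within slide 2.

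Proinflammatory cytokine and chemokine genes had medians above 0 without passing in camera on all arrays. Without a block, fry called both lists for change in either direction (adjusted p = 0.0417 and 0.0463) but neither for a shift in one direction (0.265 and 0.0962). Both lists passed in camera at the preset correlation once the slide was a block. They did not pass there with an estimated correlation (adjusted p = 0.593 each) or in fry for a shift in one direction (0.0754 each). The cytokine list had a median of 0.24 with 10 of 15 members above 0 (adjusted p = 0.0654, camera). The median was 0.26 with the slide as a block (adjusted p = 0.0224), 0.20 within slide 1 and 0.32 within slide 2. Csf3, which encodes granulocyte colony-stimulating factor, differed by 1.59 ± 0.41 (log2, SE), Il1b by 1.43 ± 0.38, Il1a by 0.90 ± 0.29 and Clcf1 by 0.60 ± 0.16, while Tnfsf10 differed by -0.71 ± 0.21. With normexp correction these were 0.65 for Csf3, 0.54 for Il1a, 0.30 for Clcf1 and -0.32 for Tnfsf10. Of the cytokine genes, adjusted over the list alone, 3 were higher without the block, and 6 were higher and 1 lower with it. The chemokine list had a median of 0.19 with 15 of 22 members above 0 (adjusted p = 0.0654, camera). The median was 0.15 with the slide as a block (adjusted p = 0.0414), 0.25 within slide 1 and 0.15 within slide 2. The neutrophil chemokine genes Cxcl2, Cxcl1 and Cxcl3 differed by 1.08 ± 0.23, 0.83 ± 0.22 and 1.24 ± 0.46, and Cx3cl1 by 0.62 ± 0.14, while Ccl4 differed by -0.46 ± 0.11. Without control 3 the difference of Cxcl3 was 0.72, and with quantile normalization the chemokine median was 0.08. Of the chemokine genes, adjusted over the list alone, 3 were higher and 1 was lower without the block, and 6 were higher and 2 lower with it. With an estimated correlation the adjusted p was 0.662 for each of these 2 lists on all arrays. The cytokine list had an adjusted p of 0.00339 without control 2 and 0.0395 without ADP 3, and the chemokine list 0.0308 without control 2. With any other array left out neither list passed. The adjusted p rose to 0.238 without control 3 and 0.307 without ADP 1 for cytokines, and to 0.236 without ADP 1 for chemokines. Both lists passed with median scaling (adjusted p = 0.0222 each) and in the unscaled value table (0.0147 each), and the cytokine list with quantile normalization (0.0243).

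**Figure D3:**
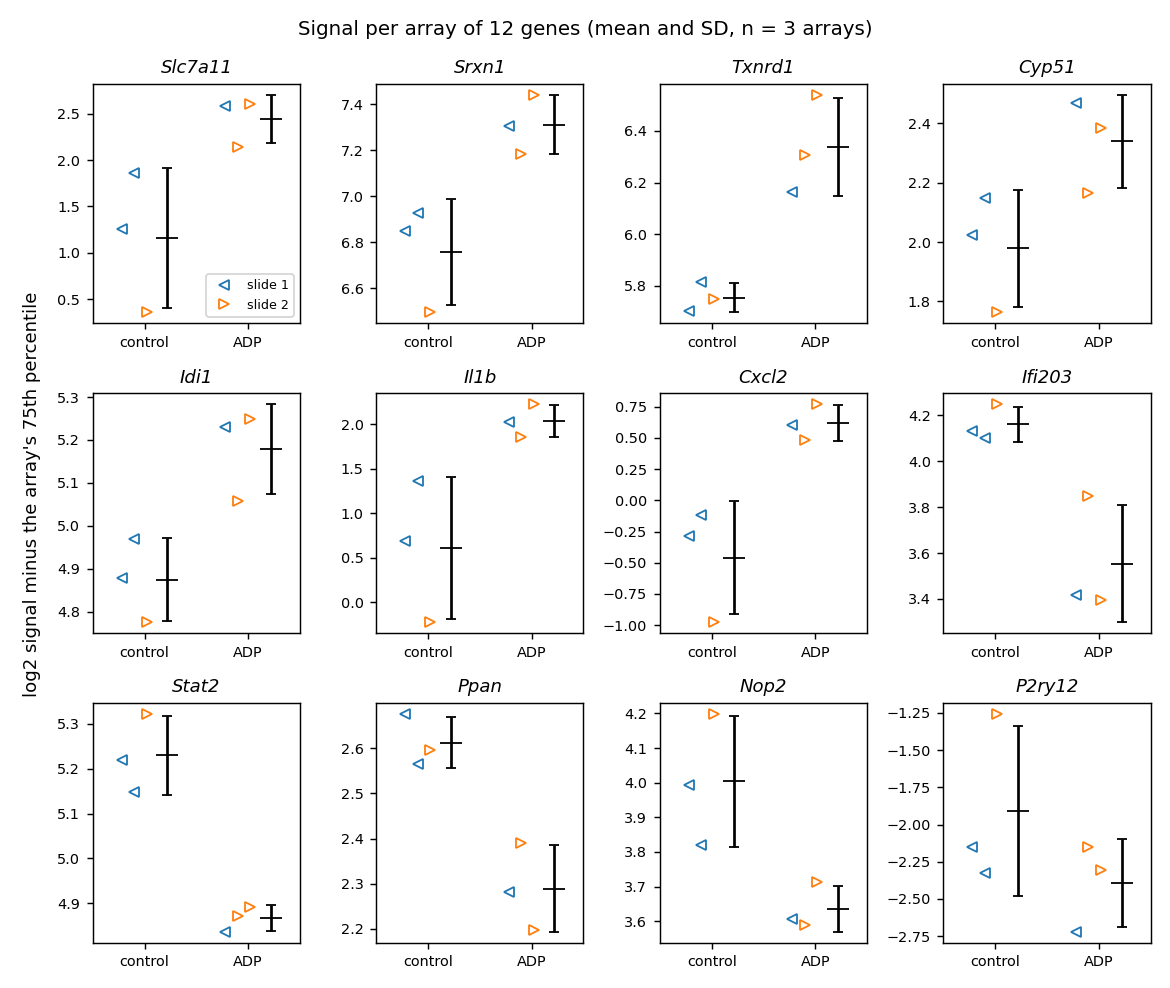
Signal of 12 genes on each array (vertical axis, log2 signal minus the array's 75th percentile, scaled separately for each gene) in control and ADP macrophages. Triangles are single arrays, pointing left for slide 1 and right for slide 2, and black bars are the mean and SD of 3 arrays. Slc7a11 lies at 1.16 ± 0.76 in controls and 2.45 ± 0.26 with ADP, and Stat2 at 5.23 ± 0.09 and 4.87 ± 0.03.

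The receptors for ADP were themselves measured. P2ry1 read 0.84 ± 0.06 in controls and 0.82 ± 0.11 with ADP (SD, n = 3 each), a difference of -0.02 ± 0.11 (log2, SE) that lay within the spread between arrays and turned sign under normexp background correction and in the unscaled value table. P2ry12 differed by -0.48 ± 0.31, with -0.73 in the slide-blocked fit and -0.49 and -0.97 within slides 1 and 2, but -0.16 without control 3, -0.32 without ADP 1 and -0.30 with normexp correction. P2ry13 differed by -0.55 ± 0.21, with -0.52 in the slide-blocked fit and -0.14 and -0.91 within the slides. Neither passed with or without the slide block at untrended variances, while the slide-blocked setting with trended, robust variances gave an adjusted p of 0.0304 for P2ry12 and 0.160 for P2ry13. Ccl2, a monocyte chemoattractant, read 5.43 ± 0.24 in controls and 5.42 ± 0.20 with ADP, a difference of -0.01 ± 0.17. It was 0.12 with the slide as a block, and it was also above 0 under normexp correction and in the unscaled value table. The purinergic receptor list did not pass (adjusted p = 0.387, camera), with a median of -0.13 (-0.20 with the slide as a block, -0.14 and -0.27 within slides 1 and 2). Its smallest p belonged to P2ry10, which was not well above background on any control array. With the main processing P2ry10 was at least 1.45-fold higher with ADP, a log2 bound of 0.54. Under normexp correction its log2 difference was 0.34, below that bound, so the bound depends on the background method. Its adjusted p was 0.0280 in the slide-blocked setting with trended, robust variances. Nucleotide and adenosine enzymes and transporters did not pass either (adjusted p = 0.302), with a median of -0.06 (-0.10 with the slide as a block, -0.01 and -0.17 within slides 1 and 2), and the nucleoside transporter gene Slc28a2 had the smallest p, at -0.71 ± 0.17.

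Among the other inflammatory lists none passed (adjusted p = 0.152 to 0.670, camera). Anti-inflammatory feedback genes had a median of 0.14 (0.15 with the slide as a block, 0.10 and 0.18 within slides 1 and 2), and the decoy interleukin-1 receptor gene Il1r2 had their smallest p, at 1.39 ± 0.38 (log2, SE). NF-κB targets had a median of 0.12 (0.07 with the slide as a block, 0.09 and 0.07 within slides 1 and 2), where Cd40 differed by -0.55 ± 0.18. Toll-like receptors and adaptors had a median of 0.03 (0.04 with the slide as a block, 0.07 and -0.02 within slides 1 and 2), where the lipopolysaccharide co-receptor gene Cd14 differed by 0.79 ± 0.17. Inflammasome genes had a median of 0.08 (0.07 with the slide as a block, 0.08 and 0.06 within slides 1 and 2), and Il1b had their smallest p. The immediate-early and ERK list, with a median of -0.05 (0.01 with the slide as a block, -0.00098 and -0.10 within slides 1 and 2), and the cAMP and CREB target list, with 0.05 (0.06 with the slide as a block, 0.13 and -0.10 within slides 1 and 2), did not pass (adjusted p = 0.926 and 0.863). Egr2 had the smallest p of the former and Id1, at -0.82 ± 0.21, of the latter.

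Metabolic and stress lists other than those above did not pass (adjusted p = 0.152 to 0.304, camera). The hypoxia list had a median of 0.11 (0.12 with the slide as a block, 0.16 and 0.09 within slides 1 and 2), with Vegfa, the vascular endothelial growth factor gene, at 1.39 ± 0.34 (log2, SE). Glycolysis genes had a median of 0.09 (0.01 with the slide as a block, 0.02 and -0.0048 within slides 1 and 2), with the lactate exporter gene Slc16a3 at 1.26 ± 0.26, and 1 member passed adjusted over the list alone. Oxidative phosphorylation genes had a median of 0.08 (0.03 with the slide as a block, 0.04 and 0.02 within slides 1 and 2), with Cox6c at 0.18 ± 0.10 (0.08 with quantile normalization). The list of LXR and PPAR lipid handling had a median of -0.07 (-0.12 with the slide as a block, -0.05 and -0.22 within slides 1 and 2). Pdk4, which restrains pyruvate oxidation, had its smallest p, was not well above background on any ADP array and was at least 1.31-fold lower there, with a log2 difference of -0.26 under normexp correction. Eicosanoid and lipid mediator genes had a median of -0.12 (-0.15 with the slide as a block, -0.05 and -0.15 within slides 1 and 2), with the prostaglandin-degrading enzyme gene Hpgd at -1.31 ± 0.26. The p53 and apoptosis list had a median of 0.18 (0.15 with the slide as a block, 0.13 and 0.08 within slides 1 and 2), with the death receptor gene Fas at 0.48 ± 0.12. Heat shock genes had a median of 0.04 (-0.01 with the slide as a block, 0.02 and -0.04 within slides 1 and 2), with Hspa1a, an inducible chaperone, at 0.99 ± 0.18 and 3 members higher adjusted over the list alone. The integrated stress and unfolded protein response list had a median of 0.09 (0.13 with the slide as a block, 0.12 and 0.08 within slides 1 and 2), with Nupr1 at 0.51 ± 0.14. In 1 alternative setting each, the lists passed for LXR and PPAR lipid handling with quantile normalization (adjusted p = 0.0424), for glycolysis with every probe on its own (0.0449) and for integrated stress with the slide as a block and quantile normalization (0.0472).

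Lists of macrophage state did not pass (adjusted p = 0.157 to 0.864, camera). Macrophage identity genes had a median of 0.04 (-0.02 with the slide as a block, -0.03 and -0.03 within slides 1 and 2), opposite in sign to the direction of the test. Alternative activation genes had a median of 0.01 (0.08 with the slide as a block, 0.10 and 0.06 within slides 1 and 2), with the transglutaminase gene Tgm2 at 1.04 ± 0.28 (log2, SE). Antigen presentation genes had a median of -0.07 (-0.05 with the slide as a block, -0.02 and -0.30 within slides 1 and 2), with the co-stimulatory gene Cd86 at 1.01 ± 0.21. Phagocytosis genes had a median of -0.05 (-0.06 with the slide as a block, 0.01 and -0.16 within slides 1 and 2), with the inhibitory Fc receptor gene Fcgr2b at -0.52 ± 0.14, and the list passed with quantile normalization alone (adjusted p = 0.0243). Lysosome and autophagy genes had a median of 0.11 (0.04 with the slide as a block, 0.07 and 0.03 within slides 1 and 2), with Tfec at 0.49 ± 0.18. Matrix remodelling and growth factor genes had a median of -0.02 (-0.09 with the slide as a block, -0.08 and 0.0014 within slides 1 and 2), below 0 while their mean, 0.16, and the test pointed higher. Timp1, an inhibitor of metalloproteinases, had the smallest p there, at 0.90 ± 0.17, and 3 members were higher and 1 lower adjusted over the list alone. Adhesion and migration genes had a median of 0.02 (0.03 with the slide as a block, 0.08 and -0.02 within slides 1 and 2), with the urokinase gene Plau at -1.04 ± 0.21. The immediate-early list above had a mean of 0.05, opposite in sign to its median and test.

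Markers of other cells that a marrow culture could hold did not pass as lists (adjusted p = 0.272 to 0.385, camera), with 5 to 13 measured members each. Mast cell, basophil and eosinophil markers had a median of 0.29 (0.11 with the slide as a block, 0.34 and 0.01 within slides 1 and 2), with Hdc, the histamine-forming enzyme gene, at 2.23 ± 0.76 (log2, SE), but at 1.32 without control 3. Lymphocyte markers had a median of 0.23 (0.05 with the slide as a block, 0.09 and -0.03 within slides 1 and 2), with Cd2 at 0.75 ± 0.25. Erythroid and megakaryocyte markers had a median of 0.20 (0.15 with the slide as a block, 0.16 and 0.18 within slides 1 and 2). Neutrophil markers had a median of 0.10 (0.06 with the slide as a block, 0.16 and -0.02 within slides 1 and 2), with S100a8 at 0.32 ± 0.12. Stromal and endothelial markers had a median of 0.04 (0.03 with the slide as a block, -0.0018 and 0.11 within slides 1 and 2), with Cdh5 at 0.33 ± 0.14. Dendritic cell markers had a median of -0.12 (-0.15 with the slide as a block, -0.12 and -0.19 within slides 1 and 2), against a mean of 0.02, with Batf3 at -0.82 ± 0.19. Monocyte progenitor markers had a median of -0.15 (-0.21 with the slide as a block, -0.22 and -0.12 within slides 1 and 2), with Kit at -0.72 ± 0.22. With normexp correction Cd2, Cdh5 and Kit were at 0.28, 0.11 and -0.35.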

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

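The counts at an unadjusted p, the list medians and the slide-blocked fits with quantile normalization or with trended, robust variances were chosen after the data were seen. The count of genes past the adjusted threshold was 0 under every setting run except the last of these, which called 1939 genes, 296 of them at least 2-fold. In 1205 of the 1939 the unadjusted p was under 0.05 without a block. Simulated data with slide shifts but no correlation between genes gave 46 false calls among 878 in that setting and 13 among 648 without a block. The slide block with untrended variances gave 46 among 879 there, because the simulated spreads had no trend with signal. The simulation therefore cannot tell how many of the 1939 are false. With the count at an unadjusted p under 0.05, 2492 on all arrays, the slide block gave 4759, the slide block with quantile normalization 4879, the slide block with trended variances 5111 and the unscaled value table gave 1554. Of the 1554, 1228 were higher and 326 lower, and the median of all genes was 0.0818 without scaling, against 0.0044 with it. Leaving out 1 array gave 1163 to 2982 (1381 without control 1, 1163 without ADP 3). The cause of these differences was not tested, except that a lone left-out array leaves fewer samples. The 6 shifted lists became 0 with an estimated correlation and 1 with fry, and stayed between 4 and 9 otherwise. In every setting with the preset correlation, each array left out included, the NRF2, cholesterol, interferon-stimulated and ribosome lists passed. The log2 difference of Ccl2 was 0.0053 with normexp, 0.069 in the value table, 0.12 with the slide block, the same with trended variances, and 0.11 with quantile normalization added, and -0.14 to 0.088 with 1 array left out. P2ry1 was at 0.074 and 0.059 under the first 2 of these and at -0.081 to 0.019 with 1 array left out. Of the lists that did not pass, the test's direction turned for the immediate-early list with median scaling (median -0.071), the value table (0.031), every probe tested (0.011), the slide block (0.0051, the same with trended variances) and the slide block with quantile normalization (0.031). It turned for antigen presentation with the mean of probes (-0.073) and every probe (-0.066), for macrophage identity with the mean of probes (0.066), for matrix remodelling with every probe (-0.033), for adhesion with quantile normalization (0.017) and for mast cell markers without a filter (-0.087). With 1 array left out, the medians of lists whose direction turned ranged from -0.056 to 0.087 (immediate-early), -0.15 to 0.026 (antigen presentation), -0.019 to 0.094 (macrophage identity), -0.056 to 0.041 (matrix remodelling), 0.0015 to 0.066 (adhesion) and -0.032 to 0.073 (cAMP targets). Over all alternatives, single named genes kept direction and side of the threshold in 1652 values, newly passed in 74 and turned in 14, and lists did so in 752, 19 and 22 and lost the call in 26. Signal over background limits genes such as Ager and P2ry10, for which only bounds exist in one group.

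Same-numbered control and ADP arrays deviated together for replicates 1 and 3 (r = 0.423 and 0.431 across genes) and apart for replicate 2 (-0.398). Controls correlated best with an ADP array of their own slide. Replicates 1 and 3 each lay on 1 slide and replicate 2 on both, so these values repeat the slide layout. They cannot tell whether same-numbered arrays share a donor. As no label says so, the numbers were not taken to pair the samples. The replicate block called 0 genes and 5 lists, with 2494 genes at an unadjusted p under 0.05, and the macrophage identity list, which did not pass, turned direction (median 0.040).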

Other observations

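The tests of trace endotoxin and of an offset between slides, those of unequal slides on 4 and 6 lists and of markers of other cells, and the genes named in this part, were chosen after the results or the slide-blocked list values were seen. The cAMP and CREB target list did not pass in fry for change in either direction (adjusted p = 0.0805), and its members are given as values only. Crem, an inducible repressor of cAMP-responsive transcription, differed by 1.55 ± 0.52 (log2, SE) on ADP against control arrays, and the phosphodiesterase genes Pde3b and Pde4d by 1.16 ± 0.30 and 0.92 ± 0.30. Rapgef3, a cAMP-activated exchange factor, differed by -0.96 ± 0.32, and the clock gene Per2 by -0.93 ± 0.26. With the slide as a block, 8 of the 21 measured members were higher and 7 lower adjusted over the list alone, and none passed without the block. Nt5e, the ecto-enzyme that makes adenosine from AMP, differed by 1.54 ± 0.50, Enpp1 by -0.58 ± 0.16, the ATP-gated channel gene P2rx7 by -0.58 ± 0.16 and the adenosine receptor gene Adora2a by 0.40 ± 0.15. Among macrophage genes, Cx3cr1, Mertk and Cebpa differed by -1.10 ± 0.29, -0.61 ± 0.18 and -0.48 ± 0.12, while Cd14 differed by 0.79 ± 0.17. Without control 3 the differences were 0.96 for Crem, 0.58 for Pde4d and 0.97 for Nt5e. With normexp correction Pde4d was at 0.49 and Per2 at -0.32, and with the mean of its probes P2rx7 was at -0.35. None of these genes had an adjusted p under 0.05 over all genes tested, with or without the slide block, in fits with untrended variances.

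The first pattern is the 2492 genes at an unadjusted p under 0.05. The split of the 6 arrays by slide gave 5747 such genes and 2819 at an adjusted p under 0.05, which points to a structure of the samples, so 2 of the 10 splits reached the real count, and 10 splits are too few for a share under 0.05. Across genes, the within-slide differences correlated at r = 0.456, but 1 of the 8 other ways to pick an odd array from each slide gave 0.463, so this test, fixed beforehand, did not set the treatment apart from differences between arrays of unequal slides, and part of those choices also holds any ADP effect. With the slide as a block, the real assignment gave 4759 genes and the highest of the 8 others 1289. The block takes out a constant offset by construction, whatever the data show, so the 4759 are no test of such an offset. Of the 2492 genes, 2361 also had an unadjusted p under 0.05 with the block, all with the same sign. That argues against a constant offset as the whole source of those 2361. The rank of the real assignment adds no conclusion, since 9 assignments are too few for a share under 0.05. The 8 others also mix the groups, so any ADP effect would widen their spread. An effect of ADP remains open, as do differences between arrays within slides.

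The second pattern is the shift of the NRF2, cholesterol synthesis, interferon-stimulated and ribosome biogenesis lists, the 4 with the smallest p in camera at the preset correlation. All 4 lost the call with an estimated correlation (adjusted p = 0.347 for NRF2 and 0.662 for the others, and 0.593 for each with the slide as a block). None of the medians, 0 of 4, lay inside the central 95% of 10000 random lists matched on signal. Genes of similar signal thus did not shift as far, which argues against an intensity-dependent bias as the whole source. For the NRF2 list the central 95% ran from 0.0030 to 0.147, wholly above 0, so genes of its signal also read somewhat higher. For the cholesterol synthesis, interferon-stimulated and ribosome biogenesis lists it spanned 0. The random lists hold no correlation between genes, and lists that did not pass, such as p53 and apoptosis and phagocytosis, also lay outside theirs. Lying outside is therefore no evidence for the shifts themselves. With the slide as a block the 4 medians were 0.22, 0.24, -0.28 and -0.31, with adjusted p of at most 6.37e-04 at the preset correlation, and within a slide their smallest size was 0.193 with no sign turned, which argues against unequal slides as the whole source of these 4 shifts, although the 4 were picked with the slide-blocked values in view. Among all 6 called lists 1, the cell cycle list, turned sign and lost its call with the block, so unequal slides stay open for it. A grouping of arrays by chance stays open too, since the real split called 6 lists and another split 5, so 1 of the 10 splits reached 6 and 2 reached 4, and 10 splits are too few for a share under 0.05. Markers of another cell type could not be excluded as moving with the lists. The largest size held with 1 sign within both slides was 0.162, for erythroid and megakaryocyte markers, short of the 0.190 of the smallest of the 4 shifts, but 4 of the 7 marker lists reached that size with 1 array left out: mast cell (0.497), lymphocyte (0.383), erythroid and megakaryocyte (0.221) and monocyte progenitor markers (-0.221, and -0.207 with the slide as a block).

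The third pattern is the medians above 0 of the cytokine and chemokine lists. Among the fits of all 6 arrays at the main scaling, their shift in 1 direction passed only with the slide as a block, and there only at the preset correlation. Without the block, fry for change in either direction called both lists (adjusted p = 0.0417 and 0.0463), but that does not test a shift above 0. Trace endotoxin in the ADP is a candidate explanation, and it would raise interferon-stimulated genes along with cytokines in macrophages. The median of the interferon-stimulated list lay below 0 within both slides, and with 1 array left out its highest value was -0.14, which argues against endotoxin as the sole source. This test was written after that list had been seen to be lower. The list's own shift did not pass with an estimated correlation (adjusted p = 0.662, camera) or in fry (0.364). Endotoxin together with an effect that lowers interferon-stimulated genes cannot be excluded. A response to ADP itself is a hypothesis that these arrays leave open.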
